A study of Oryza sativa with 12 samples.

How the data were processed

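Total RNA of rice shoots was enriched for poly(A) mRNA, fragmented and copied with random primers into sequencing libraries, per the labels' protocols. The series has 12 samples: WT and myb110 plants, SAM and leaf blade, with 3 libraries for each genotype and tissue. Each SAM library came from a pool of 20 plants, per the labels, so p-values measure the spread between pools and not between plants. The library kit is not described as marking strand, and counting is not stated to use it, so overlapping and antisense genes are uncertain.

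Reads were cleaned with fastp, per the submitters' processing notes. The aligner, the counter, the genome build and the annotation are not given in the sources used here. The SAM table holds 38867 genes, most with reference locus numbers and the rest with assembled gene numbers, and gives gene symbols, descriptions and pathway names, per the file headers. The deposited values per gene and library are estimated counts, per the file headers, and 12.3% to 13.2% of the values in a library were not whole. The authors also deposited FPKM, counts scaled for gene length and library size, per the file headers, and which lengths and fragments entered is not stated. Gene names were taken from the table. No genome was used here, and chromosome and order along it were read from the locus numbers, so no coordinates are given.

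SAM columns were matched to samples by genotype and number in their names. The tissue of this table rests on its name. The column names of the blade table could not be matched to labelled genotypes, so the blade, the comparison of the tissues and the test of a different effect per tissue were not analysed here. In all, 24 columns of per-sample values were not used, 6 of them in the SAM table.

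The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 23167. Libraries were scaled by TMM, with factors from 0.998 to 1.00, and myb110 was compared with WT by edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3), Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Positive log2 changes are higher in myb110. Errors beside them are standard errors, taken as the absolute log2 change over the square root of edgeR's F. They borrow spread across genes, with n = 3 per genotype. CPM were computed from library totals over the kept genes, scaled by the TMM factors. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group, with the other group's counts taken as exact. Intervals and floors cover counting error only, since reads were not tagged by molecule.

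Before the data were examined, 16 gene lists with 221 loci, 11 annotated pathways, the tests and the rule for naming genes were fixed. The lists cover photoperiodic flowering, phase change and inflorescence identity, floral organ identity, the clock, shoot meristem, lateral organ and mesophyll markers, the secondary cell wall, cell division, gibberellin, phosphate starvation, nitrogen, defence, diterpenoid phytoalexins, heat shock proteins and leaf senescence. GID2 and CYCD3;1 were dropped because the table annotates these loci as other genes, and FON2 was absent. Lists with 5 or more tested members were tested with limma's camera (limma 3.58.1, preset correlation 0.01) and, beside it, camera with an estimated correlation and fry, with adjustment over the lists. Pathways of 10 to 500 tested genes were tested for enrichment by one-sided Fisher exact tests, against the tested genes with any pathway.

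The rule names MYB110, MADS15 and Nhd1, and then the 8 largest rises and 8 largest falls among annotated genes that passed, with separate genotypes and at least 5 CPM in a group. It adds up to 2 members each way per list by lowest p, and up to 4 for the flowering and inflorescence lists. Named beyond the rule, after their values were seen, were YAB6, ZTL2, PRR1, PRR59, PRR73, KS1, KAO, GA20ox1, HSP17.9A, HSP18.0, HSP90-1, CYCB1;1, SPX1, LHCA5, MADS2, GAPB, RCA, RBCS4, PSBR, the copies of TON1B, Os12g0102500 and the second copies of LTP110-A and ALY1. Some list members are not reported here by name.

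Depth ran from 14112966 to 18896372 counts per library. Correlations of log CPM were 0.984 to 0.987 within genotypes and 0.942 to 0.949 between them. No pair of libraries of a genotype differed by as little as counting noise, with a chi-square of 2.14 to 2.67 per gene. The biological coefficient of variation was 0.0465. The steps were tested on simulated counts for the 23167 genes of the SAM comparison. edgeR recovered 54 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 5 false calls. DESeq2 recovered 67.2%, 86.6% and 97.0%, with 0 false calls, and limma 82.1%, 92.5% and 98.5%, with 6. Of 400 simulated lists of 20 unchanged genes, camera called 0. The simulated genes were drawn independently with a common dispersion. The simulation therefore does not cover lists whose members vary together, or differences in dispersion between genes.

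The alternatives were RLE factors, no filter on low counts, a block for the replicate number, each replicate left out in turn, at least 2-fold changes, DESeq2 1.42.0, and limma on log2 of FPKM plus 1 or plus 0.1 with a mean of at least 1 FPKM in a genotype. On the log2 FPKM scale a pseudocount understates the change of low genes. DESeq2 gave no adjusted p for 12619 genes, which were left out of its counts. Counts that were not rounded, the fit without the windows of very large changes, and most alternatives for lists and pathways were added after seeing the data.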

Results

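RNA-seq libraries were made from rice (Oryza sativa) plants with an intact MYB110 gene, called wild type (WT), and from a myb110 mutant. MYB110 is a MYB transcription factor, and the series places it in a flowering-time module with Nhd1, a clock-type MYB factor, and MADS15, a MADS-box factor of the floral meristem. Shoot apical meristem (SAM) and new leaf blade were collected 1 month after transplanting. The comparison reported here is myb110 against WT in the SAM, with 3 libraries per genotype, each from a pool of 20 plants. The blade libraries are not analysed here. Total deposited counts per SAM library ran from 14112966 to 18896372, and 23167 genes had enough counts to be tested. The tissue of the table used is known only from the name of the table, whose columns give genotype and number.

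The locus taken here as MYB110, Os10g0478300, which the deposited annotation names MYB4, had few counts in any library. That it is the mutated gene rests on general knowledge and was not checked against a source. The 3 WT libraries held 6, 0 and 1 counts and the 3 myb110 libraries 0, 0 and 0. With the mutant set to the floor of 3 counts, the WT group was 2.21-fold higher, which takes the 7 WT counts as exact. Of these 7 counts, 6 came from 1 library. The locus did not reach the count filter, so it gives no check of the genotype labels, and a difference was not detectable at this depth. A fit without the filter gave an edgeR adjusted p of 0.139.

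MADS14, MADS15 and MADS18, related MADS-box genes that specify inflorescence and floral meristems, fell in the mutant. The MADS-box genes MADS20 and MADS47 of the same list rose, as given in the next paragraph. MADS15 (Os07g0108900) had 2.89 ± 0.123 CPM (counts scaled to library size, mean ± SD, n = 3) in WT and 0.141 ± 0.122 CPM in myb110, from 144 and 6 counts. It fell by 4.41 ± 0.51 (SE) on the log2 scale, with an edgeR adjusted p of 1.09e-08, and the lower bound of the 95% counting interval of the ratio was 10.2. MADS14 fell by 1.85 ± 0.08, from 49.8 ± 3.15 to 13.8 ± 1.87 CPM. MADS18 fell by 0.51 ± 0.05, from 89.3 ± 2.65 to 62.7 ± 3.11 CPM. RCN4, a homolog of the flowering repressor TERMINAL FLOWER 1, fell by 0.79 ± 0.18.

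Other regulators of the same phase change rose. SPL14, a squamosa-promoter-binding factor that shapes panicle branching, rose by 0.39 ± 0.03 on the log2 scale, from 333 ± 6.87 to 434 ± 9.77 CPM. MADS47 rose by 0.27 ± 0.06, TAW1, which delays the spikelet fate, by 0.15 ± 0.03, and MADS20 by 1.00 ± 0.23 at 2.13 ± 0.0764 CPM in WT. Of the 17 tested members of the list of phase change and inflorescence genes, 6 rose, 6 fell and 5 did not pass, and 15 passed when adjusted over the list alone. The list as a whole did not pass the test for moving one way against other genes (camera adjusted p = 0.753).

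**Figure D1:**
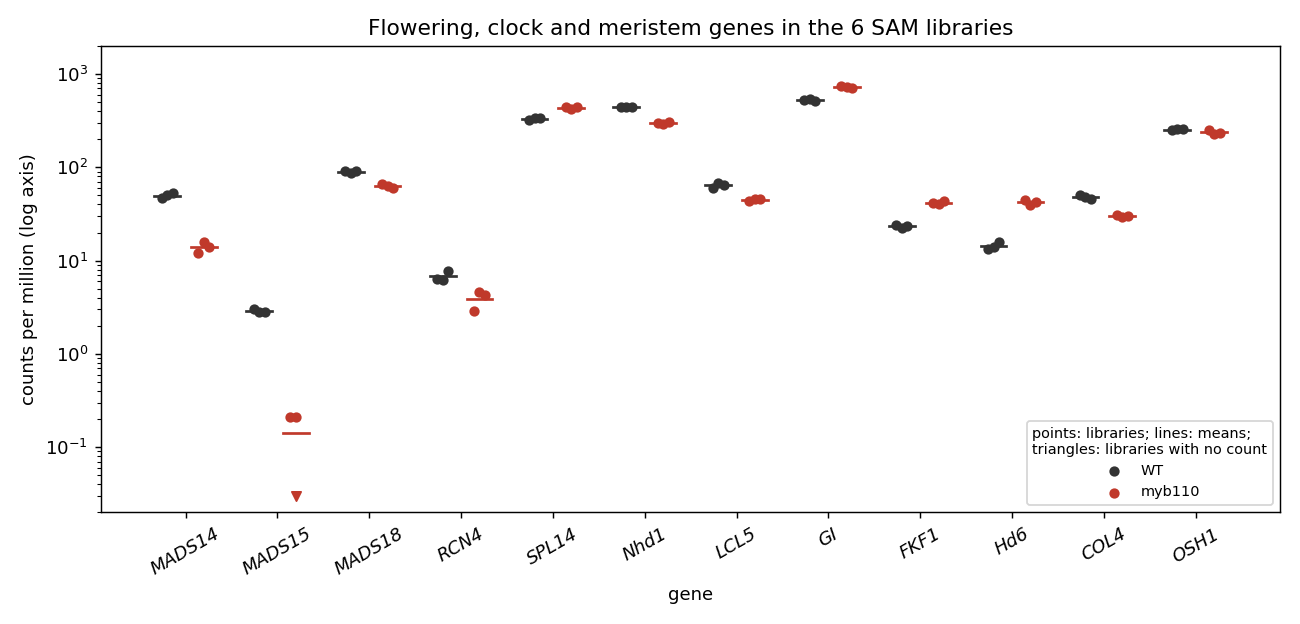
CPM (log axis) of 12 flowering, clock and meristem genes in the 3 WT and 3 myb110 SAM libraries; points are libraries, horizontal lines are group means, and the triangle marks a library with no count, drawn at the bottom of the axis. MADS14 lies at 49.8 CPM in WT and 13.8 CPM in myb110, while the meristem gene OSH1 lies at 254 and 238 CPM.

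Among photoperiodic flowering regulators, the genes that rose included Hd6, GI and FKF1, and those that fell were Nhd1 and COL4. Nhd1 (Os08g0157600, annotated as LHY) fell by 0.56 ± 0.03 on the log2 scale, from 442 ± 1.94 to 299 ± 7.60 CPM (edgeR adjusted p = 6.34e-19). COL4, a CONSTANS-like repressor of flowering, fell by 0.67 ± 0.07, from 48.4 ± 2.46 to 30.4 ± 0.817 CPM. Hd6, the alpha subunit of casein kinase 2, rose by 1.55 ± 0.08, from 14.4 ± 1.22 to 42.2 ± 2.14 CPM. GI, a clock-controlled activator, rose by 0.45 ± 0.02 and the blue-light F-box gene FKF1 by 0.85 ± 0.07, while phytochrome gene PHYA rose by 0.26 ± 0.04. In this list 6 of the 17 tested members rose, 2 fell and 9 did not pass, and 10 passed when adjusted over the list alone (camera adjusted p = 0.321). The florigen gene Hd3a and the regulators Ehd1 and Ghd7 were below the filter.

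The clock genes overlapped with this group and moved both ways. Those that fell were Nhd1, LCL5, a MYB-like gene related to it, by 0.54 ± 0.06, and the F-box genes ZTL1 and ZTL2 by 0.23 ± 0.05 and 0.11 ± 0.04. The pseudo-response regulator genes PRR1 and PRR59 rose by 0.43 ± 0.07 and 0.33 ± 0.07, and PRR73 by 0.20 ± 0.03. Of 14 tested clock genes, 6 rose, 4 fell and 4 did not pass, and 12 passed when adjusted over the list alone. The list did not pass (camera adjusted p = 0.763), and neither did the annotated plant circadian rhythm pathway (camera adjusted p = 0.172). That pathway shares 12 tested genes with the list and had 11 members that rose and 4 that fell of 34. The ZTL2 call was lost without WT replicate 1 or 2 (edgeR adjusted p = 0.0679 and 0.0661) or myb110 replicate 2 or 3 (0.101 and 0.0642) and in limma on FPKM, and ranged from 0.0146 to 0.101 over all alternatives.

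Genes of the photosynthetic apparatus fell together in the mutant SAM. Of 23 tested mesophyll photosynthesis markers, 22 fell, none rose and 1, LHCA5, did not pass (-0.52 ± 0.39), and the median log2 change was -1.48. The same 22 passed when adjusted over the list alone. The antenna genes CAB2R and CAB1R fell by 2.18 ± 0.05 and 1.58 ± 0.05, from 143 ± 7.03 to 31.6 ± 0.628 CPM and from 134 ± 8.16 to 44.6 ± 0.361 CPM. The photosystem II genes PSBO and PSBP fell by 1.80 ± 0.07 and 1.37 ± 0.06. The carbon fixation genes GAPB and RCA, the latter encoding Rubisco activase, fell by 0.37 ± 0.09 and 0.65 ± 0.12. The list fell against other genes (camera adjusted p = 2.53e-69), also with an estimated correlation (adjusted p = 0.00856).

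The Rubisco small subunit genes had few counts, with RBCS4 at 2.96 ± 0.279 CPM in WT and 1.61 ± 0.157 CPM in myb110. The RBCS4 call was lost without WT replicate 3 (edgeR adjusted p = 0.0630) or myb110 replicate 2 or 3 (0.0571 and 0.0531), and ranged from 0.0145 to 0.0630 over all alternatives.

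The annotated photosynthesis pathways gave the same direction, and they share genes with the marker list. In the antenna protein pathway 12 of 14 tested genes fell and none rose (camera adjusted p = 5.02e-64, and adjusted p = 0.00856 with an estimated correlation), and 13 of the 14 are also in the marker list. In the photosynthesis pathway 26 of 39 fell and 1, the ferredoxin gene FDX6, rose by 0.24 ± 0.08 (camera adjusted p = 1.36e-19, and adjusted p = 0.00856 with an estimated correlation). The FDX6 call was lost without WT replicate 1 (edgeR adjusted p = 0.0720), WT replicate 2 (0.0918) or myb110 replicate 2 (0.226) and in limma on FPKM, and ranged from 0.00864 to 0.226 over all alternatives.

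Markers of the meristem and of lateral organs, measured beside these genes, moved little or both ways. Of 6 tested meristem markers, 5 did not pass and OSH1, the KNOX gene of the meristem, fell by 0.09 ± 0.03, from 254 ± 3.76 to 238 ± 9.44 CPM. That call was lost without WT replicate 2 or 3 (edgeR adjusted p = 0.105 and 0.0691), without myb110 replicate 2 or 3 (0.227 and 0.119) and in limma on FPKM, and ranged from 0.0123 to 0.227 over all alternatives. Of 7 lateral organ primordium markers, 2 rose and 3 fell, with a median log2 change of 0.02. YAB3 fell by 0.51 ± 0.14, YAB6 by 0.36 ± 0.12 and PLA1 by 0.20 ± 0.06, whereas DL rose by 0.51 ± 0.17 and YAB5 by 0.21 ± 0.07. Neither list passed (camera adjusted p = 0.920 for each).

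Among these primordium markers only the PLA1 call held without each library in turn. DL was lost without WT replicate 3 (edgeR adjusted p = 0.0828) or myb110 replicate 3 (0.0899), with a range of 0.00992 to 0.0899 over all alternatives. YAB3 was lost without WT replicate 1 (0.0621) or myb110 replicate 1 (0.0597), with a range of 0.00380 to 0.0621. YAB6 was lost without WT replicate 1 or 3 (0.0718 and 0.0956), without myb110 replicate 2 or 3 (0.171 and 0.0526), in DESeq2 and in limma on FPKM, with a range of 0.0226 to 0.171. YAB5 was lost without WT replicate 1, 2 or 3 (0.142, 0.0515 and 0.0586), without myb110 replicate 1 or 2 (0.122 and 0.158) and in DESeq2, with a range of 0.0177 to 0.158. Among floral organ genes, 3 were tested, MADS16 rose by 0.27 ± 0.04 and DL rose, MADS2 did not pass (0.24 ± 0.18), and the list had too few tested members for a list test, except without the filter (camera adjusted p = 0.564).

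**Figure D2:**
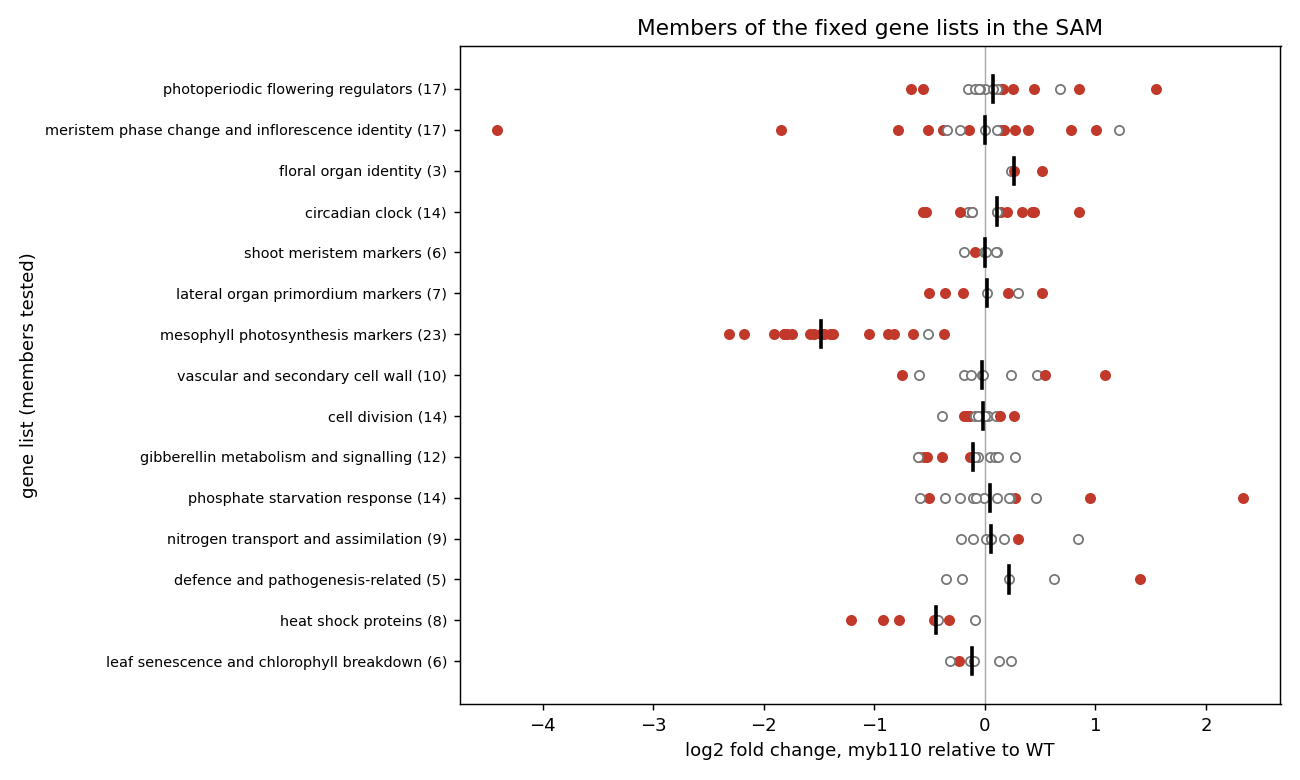
Log2 fold change of myb110 relative to WT for each tested member of the fixed gene lists; filled points passed the test, open points did not, black bars are list medians, and the number tested stands beside each name. The mesophyll photosynthesis markers have a median of -1.48 and the shoot meristem markers a median of -0.00.

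Of 8 tested heat shock protein genes 5 fell, 3 did not pass and none rose (camera adjusted p = 0.00363), and the list call was lost with an estimated correlation (adjusted p = 0.156). HSP101, a disaggregating chaperone, fell by 0.93 ± 0.06, from 68.8 ± 4.05 to 36.3 ± 2.20 CPM. HSP90-1 fell by 0.78 ± 0.13, and the small heat shock genes HSP17.9A, HSP18.0 and HSP18.6 fell by 1.21 ± 0.29, 0.46 ± 0.08 and 0.32 ± 0.05. The abundant chaperone genes HSC-2 and HSP70-4 of the endoplasmic reticulum pathway also fell, by 0.46 ± 0.02 and 0.44 ± 0.03. That pathway had 24 members that rose and 27 that fell of 185 and did not pass (camera adjusted p = 0.770).

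Ribosomal protein genes that changed rose in most cases, by small amounts. Of 291 tested, 113 rose and 14 fell, with a median log2 change of 0.10 (camera adjusted p = 0.000482), and the call was lost with an estimated correlation (adjusted p = 0.609). RPL35 rose by 0.57 ± 0.02 and RPS15AA by 0.38 ± 0.03, whereas RPS27, whose locus number follows that of RPS15AA, fell from 103 ± 6.17 to 24.1 ± 1.74 CPM. Phenylpropanoid genes rose in 29 and fell in 13 of 115 cases (camera adjusted p = 0.0154), a call also lost with an estimated correlation (adjusted p = 0.182). PAL, which starts the pathway, rose by 0.55 ± 0.03, from 282 ± 5.03 to 413 ± 8.18 CPM, and the beta-glucosidase gene BGLU9 rose by 3.23 ± 0.09.

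In the gibberellin list 5 of 12 tested genes fell, 7 did not pass and none rose, and the list did not pass (camera adjusted p = 0.113, and adjusted p = 0.360 with an estimated correlation). CPS1, the first committed enzyme, fell by 0.53 ± 0.06, the later enzymes KS1 and KAO by 0.55 ± 0.08 and 0.59 ± 0.15, GA20ox1 by 0.13 ± 0.05 and the receptor gene GID1 by 0.39 ± 0.04. GID1 went from 158 ± 2.36 to 120 ± 1.22 CPM. The list passed at 0.0301 without the windows of very large changes described at the end, an alternative chosen after seeing the data, and in fry, which compares a list with no other genes. GA20ox1 was lost without WT replicate 2 (edgeR adjusted p = 0.232), without myb110 replicate 1 or 3 (0.141 and 0.104), in DESeq2 and in limma on FPKM, with a range of 0.0223 to 0.232, and KAO was lost in DESeq2 (0.0753, with a range down to 6.64e-06). In the hormone signalling pathway 30 rose and 31 fell of 193, among them the auxin genes SAUR50 and LAX2, which rose by 1.02 ± 0.09 and 0.53 ± 0.05 (camera adjusted p = 0.770).

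In the phosphate starvation list IPS1, SPX1 and SPX5 rose and SPX-MFS1 fell, of 14 tested (camera adjusted p = 0.515). The non-coding RNA gene IPS1 rose by 0.95 ± 0.06, and SPX5 by 2.34 ± 0.52 from 12 counts in WT and 59 in myb110. SPX1 rose by 0.27 ± 0.09, a call lost without WT replicate 1 or 3 (edgeR adjusted p = 0.0859 and 0.0509) or myb110 replicate 1 or 3 (0.0555 and 0.0936), with a range of 0.0201 to 0.0936. SPX-MFS1 fell by 0.50 ± 0.18, a call lost without WT replicate 2 or 3 (0.218 and 0.0556), without myb110 replicate 1 or 3 (0.0987 and 0.103), in DESeq2 and in limma on FPKM, with a range of 0.0304 to 0.218. In the nitrogen list NADH-GOGAT1 rose by 0.30 ± 0.06 and the other 8 of 9 tested members did not pass (camera adjusted p = 0.763).

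In the secondary cell wall list the lignin gene CCR1 fell by 0.75 ± 0.21, the NAC factor gene SWN1 rose by 1.09 ± 0.36, and 7 of 10 did not pass (camera adjusted p = 0.770). CCR1 was lost without myb110 replicate 3 (edgeR adjusted p = 0.0873, with a range down to 0.00162). SWN1 was lost without WT replicate 1 or 3 (0.112 and 0.126), without myb110 replicate 1 or 2 (0.0854 and 0.0790) and in limma on FPKM, with a range of 0.00177 to 0.126. In the cell division list of 14, the helicase genes MCM7 and MCM6 rose by 0.26 ± 0.05 and 0.14 ± 0.05, and CYCB2;2, CYCB1;1 and CDKB2;1 fell by 0.19 ± 0.05, 0.16 ± 0.05 and 0.13 ± 0.04 (camera adjusted p = 0.920). MCM6 was lost without WT replicate 1 or 3 (0.0749 and 0.207), without myb110 replicate 2 or 3 (0.116 and 0.209), in DESeq2 and in limma on FPKM, with a range of 0.0203 to 0.209. CYCB1;1 was lost without WT replicate 2 (0.130) or myb110 replicate 1 or 3 (0.0540 and 0.0669), with a range of 0.00913 to 0.130, and CDKB2;1 without myb110 replicate 1 (0.0889, with a range down to 0.00662).

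In the leaf senescence list the chlorophyll b reductase gene NYC1 fell by 0.24 ± 0.07 and the other 5 of 6 did not pass, and in the defence list JIOsPR10 rose by 1.40 ± 0.46 and the other 4 of 5 did not pass (camera adjusted p = 0.770 for each list). NYC1 was lost without WT replicate 2 (edgeR adjusted p = 0.0537) or myb110 replicate 1 (0.0626), with a range of 0.0105 to 0.0626. JIOsPR10 was lost without WT replicate 2 or 3 (0.180 and 0.0992), without myb110 replicate 1, 2 or 3 (0.0823, 0.0647 and 0.0735) and in DESeq2, with a range of 0.00522 to 0.180. The diterpenoid phytoalexin list had 10 members in the table and none with enough counts. The annotated pathways of DNA replication, nitrogen metabolism, starch and sucrose metabolism and plant-pathogen interaction gave camera adjusted p of 0.770, 0.920, 0.920 and 0.515.

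Over all genes, 5233 of 23167 changed at an edgeR adjusted p below 0.05, 2523 upward and 2710 downward. Most were small: 3678 changed by less than 1.5-fold, and 840 changed at least 2-fold, of which 324 rose and 516 fell. The genotypes did not overlap at 36.1% of tested genes, against 10% expected by chance for 3 against 3. The first principal component held 70.7% of the variance and separated the genotypes. In a test of pathway enrichment, genes that rose were enriched in the ribosome (113 of 291, with 40.3 expected, Fisher exact adjusted p = 4.21e-26), ribosome biogenesis (27 of 90) and phenylpropanoid pathways. This test takes genes as independent, and the ribosome list was lost in camera with an estimated correlation (adjusted p = 0.609). Genes that fell were enriched in the photosynthesis (26 of 39), antenna protein (12 of 14) and carbon fixation pathways (28 of 76, with 9.59 expected, Fisher exact adjusted p = 2.70e-06). Among genes changed at least 2-fold, only the photosynthesis and antenna protein enrichments held, and those of the ribosome (0 of 291), ribosome biogenesis (3 of 90) and carbon fixation (4 of 76) were lost, each with an adjusted p of 1. The phenylpropanoid enrichment (Fisher exact adjusted p = 0.0277) was lost without WT replicate 2 (0.149) or WT replicate 3 (0.0732), without the windows described next (0.0543) and with other tools, with no filter or at least 2-fold.

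The largest changes were all-or-none in many cases. PAE1 (a pectin acetylesterase name, on an assembled gene outside the reference loci), ATG8D (Os11g0100100), an autophagy gene, and ALY1 (Os11g0100200) had 0 counts in WT and 11.5 ± 0.857, 11.1 ± 1.30 and 10.9 ± 0.931 CPM in myb110, at least 193-, 186- and 182-fold higher. A receptor kinase gene, Os11g0102900, had 0.0591 ± 0.102 CPM in WT and 145 ± 3.31 CPM in myb110, while Os12g0102500, annotated as the same kinase, fell from 240 ± 2.39 to 108 ± 1.75 CPM, and their sum went from 240 ± 2.34 to 252 ± 4.98 CPM. Conversely RPS9B (Os03g0379500) went from 26.4 ± 1.57 to 0.0237 ± 0.0410 CPM, the disease resistance gene RGA5 (Os11g0687800) from 25.6 ± 2.35 to 0.0237 ± 0.0410 CPM, and the lipid-transfer protein gene LTP110-A (Os12g0114800) from 141 ± 6.35 to 0.236 ± 0.250 CPM. The mutant-to-WT order was the same in all 6 libraries for each of these genes, which the naming rule required of the largest changes. ATG8D, ALY1, LTP110-A and this kinase share their annotated name with another gene of the table, so their counts are uncertain where reads could be split. The other ATG8D gene (MSTRG.28308) went from 8.70 ± 0.796 to 0 CPM. The other ALY1 gene (Os12g0100100) went from 73.8 ± 8.42 to 10.5 ± 0.774 CPM, so that the sum of both went from 73.8 ± 8.42 to 21.4 ± 0.817 CPM. The other LTP110-A gene (Os11g0115100) went from 182 ± 0.369 to 458 ± 4.82 CPM, and the sum of both went from 323 ± 6.02 to 458 ± 5.07 CPM.

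Genes changed by a fitted factor of at least 16 numbered 210, of which 81 had a group at 0 counts and 62 a group at 1 to 3. For 184 of the 210, the bound or the lower limit of the counting interval was also at least 16. Of the 210, 161 are reference loci. In windows of 50 tested loci along the chromosomes, 18 of 453 windows held 3 or more such loci. These 18 windows held 4.03% of the loci and 64.0% of the large changes. They were chosen by their large changes, so a high share in them was built in. Of the genes named above, Os11g0100100, both ALY1 genes, Os11g0102900, Os12g0102500, RGA5, Os12g0114800, RPS15AA, RPS27 and SAUR50 lie in such windows, and MADS15 and the other flowering and photosynthesis genes named above do not. MADS15 is itself a large change, the only 1 in its window, and the windows after it on chromosome 7 hold 1, 0, 2 and 1. Its place outside the windows thus rests on the cutoff of 3.

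**Figure D3:**
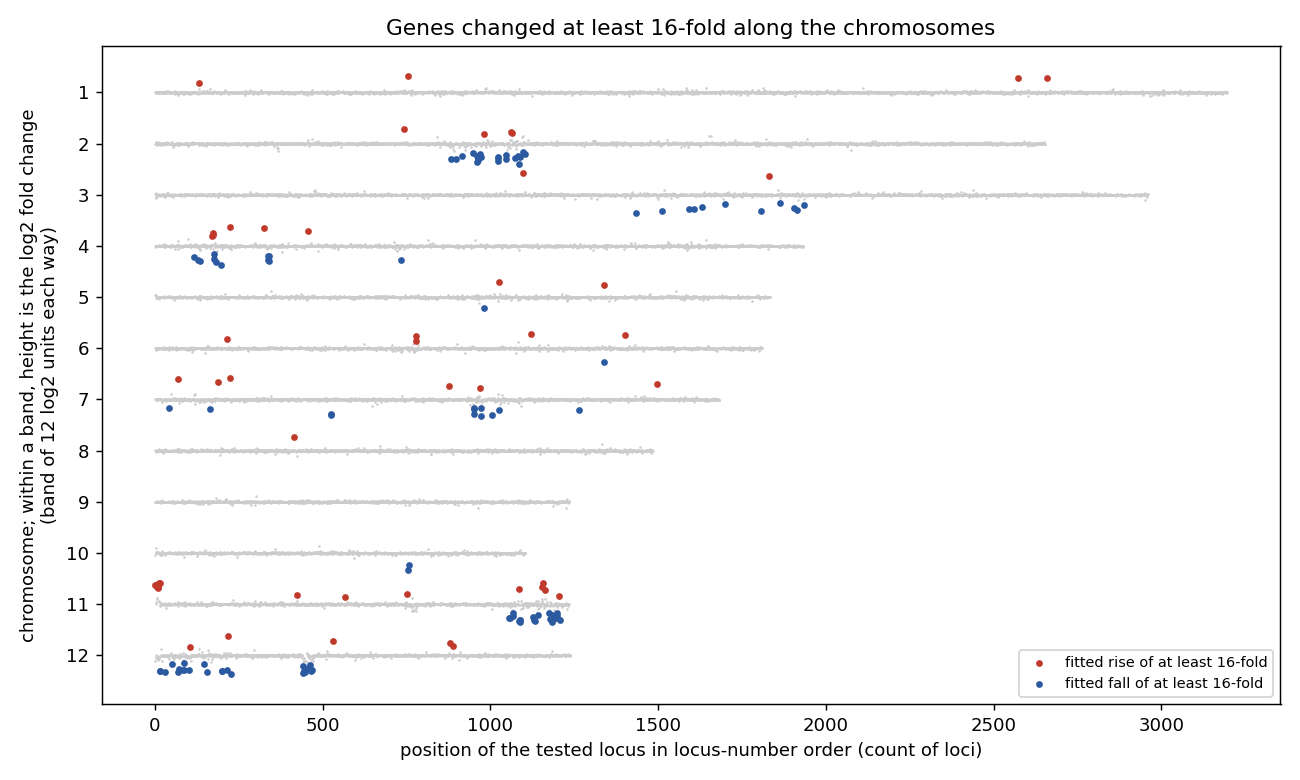
Tested loci in locus-number order along the 12 chromosomes; within each band the height is the log2 fold change, coloured points are genes with a fitted rise (red) or fall (blue) of at least 16-fold, and grey points are all other tested loci. Of the 161 coloured loci, 59.0% have another among the 5 tested loci on each side, and 71 lie on chromosomes 11 and 12.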

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

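The fit without windows of large changes and the fit on counts that were not rounded were chosen only after the result was seen, as were most alternatives for lists and pathways. The count of genes changed in SAM was 5233, of which 5217 were shared with RLE factors (5232 called), 5133 with no filter (5584) and 4911 with the replicate block (4976). Leaving out each library in turn gave 4185 to 4698, DESeq2 4656, limma on FPKM 4169 and 4083 with pseudocounts of 1 and 0.1, the fit without windows 4753 and the fit without rounding 5237. Asking for at least 2-fold left 840, fewer by construction. Rises made up 46.9% to 52.0% of calls over these fits and 38.6% of the calls of at least 2-fold, and the median log2 change of all genes stayed within 0.01 of 0. The block rests only on replicate numbers. Deviations of same-numbered libraries had correlations of -0.0469, -0.0407 and 0.0107, so the numbers do not pair the samples, and not every sample correlated best with its own number. The block changed no call of a named gene or list. Gene lists called stayed at 6 with each library left out, with RLE factors, no filter, the replicate block and no rounding, and numbered 7 without the windows, which added gibberellin. With an estimated correlation 3 remained, all of them photosynthesis lists, and fry, which compares a list with no other genes, called 16. Enriched pathways numbered 6, and 5 or 6 without each library, 7 with the replicate block, where sulfur metabolism was added, and 2 at least 2-fold, photosynthesis and antenna proteins. The cause of these differences was not tested. Medians, means and tests differed in sign for the meristem, primordium, cell wall, starch and circadian rhythm pathway lists, none of which passed. Over 111 named genes, 1453 of 1539 values under alternatives kept their call and direction, 86 lost the call and 0 reversed. Of the named genes, 15 have no value without the windows. Not run, because blade columns were not matched, were the blade, interaction, tissue, overlap and 12-library alternatives. MYB110 in the SAM lay below the filter and has no value to compare. Depth limits the genes near the floor: MADS15 rests on 6 mutant counts.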

Other observations

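Of the tests below, all but those of tandem gene families, of the windows against photosynthesis and of the splits of the libraries were chosen only after the result was seen.

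The alpha carbonic anhydrase genes ACA1 and ACA7 of the nitrogen metabolism pathway fell by 0.93 ± 0.07 and 1.18 ± 0.18 on the log2 scale (SE, n = 3), ACA1 from 38.5 ± 0.469 to 20.3 ± 0.628 CPM. BCA2 of the same pathway rose by 0.57 ± 0.19, a call lost without WT replicate 1 or 3 (edgeR adjusted p = 0.0683 and 0.0995), without myb110 replicate 1 or 3 (0.0773 and 0.133) and in DESeq2, with a range of 0.0234 to 0.133. The starch and sucrose pathway had 16 members that rose and 27 that fell of 132 and did not pass (camera adjusted p = 0.920). In it WAXY, the granule-bound starch synthase that makes amylose, fell by 0.41 ± 0.03, from 605 ± 17.7 to 454 ± 6.28 CPM. The cytokinin receptor gene HK4 fell by 0.37 ± 0.04. PHF1, which helps phosphate transporters leave the endoplasmic reticulum, rose by 0.33 ± 0.05. In the plant-pathogen pathway the calcium-dependent kinase gene CPK21 rose by 3.64 ± 0.23, from 38 to 457 counts, and the resistance gene RPP13L3 (Os11g0639600), which lies in a window of large changes, went from 53.8 ± 1.31 to 0.136 ± 0.192 CPM.

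Many of the genes changed at least 16-fold sat close to others along the chromosomes. Of 161 such loci, 59.0% had another among the 5 tested loci on each side, more than in any of 10000 shuffles, whose mean was 6.96% (permutation p = 0.0001, the smallest these can give). Loci that share an annotation with a close large-change locus were then left out. Of the remaining 155 loci, 56.8% had such a neighbour, above the highest shuffle, 18.7%. This met the criterion set beforehand against tandem gene families regulated together. Such families still stay open, because only 54 of the 161 have a symbol or a description that names a product, and only 6 were left out. Chromosome segments from different parents in the mutant and WT plants are a candidate explanation that these values go with, and a sequence check would be needed to test it further. At the starts of chromosomes 11 and 12, which are near-copies of each other, TON1B, in windows of large changes on both, had 12.9 and 225 CPM in WT and 112 and 106 CPM in myb110 on chromosomes 11 and 12, so that reads moved between near-identical copies may account for part of the changes there. Of the 16 copy pairs with both changed, 11 moved in opposite directions, and in 8 of these, 50% of the 16, the sum changed by under 1/2 of the smaller single change; the pairs that moved the same way could not meet this, so the share leaves it open.

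The fall of photosynthesis genes was weighed against the same segments and against tissue makeup. None of the 22 fallen markers lies in a window of large changes, 0%, where 4.03% of all loci lie. This argues against these 22 markers lying in segments from different parents that the windows mark, though not against a regulator in one. With 22 genes, 0% is not shown to lie below the share of all loci. The windows held 64.0% of the large changes, so segments outside them are not covered. In the photosynthesis pathway the fit without the windows kept 37 of the 39 tested genes, and 25 rather than 26 fell. The largest fall in that pathway, PSBR (-5.01), is itself a large change outside the windows. The 7 lateral organ markers had a median log2 change of 0.016 and ran from -0.51 to 0.51. The median of 13 antenna genes was -1.55. The spread over the 7 markers gave a standard error of 0.14 for their mean, which treats genes as independent. These values argue against fewer leaf primordia in the mutant samples, if primordium markers would then fall as much as the antenna genes. That condition was not tested, and among the calls of these markers only that of PLA1 held without each library in turn. Less leaf blade or sheath tissue in the mutant samples stays open: the median of 3 RBCS genes lay 0.68 ± 0.50 (SE) above that of 13 antenna genes, and these RBCS genes summed to only 6.34 ± 0.350 CPM in WT, against 875 ± 35.5 CPM for antenna genes. An effect of the myb110 genotype itself also stays open. So does collection of the mutant samples at another time of day, which was not tested for these genes.

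The clock genes changed both ways, and mutant samples collected at another time of day than WT samples could give such a pattern, as could a shifted clock in the mutant. Across 9 of the 14 tested clock genes, which are not independent, the log2 change and the textbook order of daily peaks had a Spearman rho of 0.865. Both the genes and their order were chosen after the values were seen, so this value describes them and tests nothing. The harvest time is not in the labels and would go with genotype, so the explanations cannot be told apart.

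The real split of the 6 libraries gave 5233 changed genes, and the highest of the other splits 0 (edgeR). At an unadjusted p below 0.05 the real split gave 7621 genes and the others 346 to 499, and DESeq2 called 4656 in the real split and 0 to 7 in the others. Of the 10 splits, 1 gave as many genes. It gave 6 changed lists, and the highest other split 4, and again 1 of the 10 gave as many. Each of the 9 other splits still called 3 or 4 lists with camera's preset correlation, the 3 photosynthesis lists among them, with 0 changed genes in edgeR. These splits are too few for a share under 0.05. Each of the 9 others holds both genotypes in both groups, so the genotype difference adds to the spread within groups and lowers the calls. The genotypes also stay unbalanced between the groups, so the lists called there cannot be read as chance calls.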
